A study of Mus musculus with 78 samples.

How the data were processed

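The series held 78 libraries of mouse cartilage engineered in culture, 39 for mRNA and 39 for small RNA, each in 13 groups of 3 (replicates a, b and c). Per the labels total RNA was isolated with the mirVana kit for small RNA and a Norgen kit for mRNA, the mRNA libraries were made with the Ribo-Zero Gold kit, and the small RNA libraries with an Illumina small RNA kit. The submitters' processing notes name Trimmomatic, cutadapt, STAR, featureCounts and the genome build mm10, with no version and no statement of which step each tool did. The strand setting, the annotation version and the way reads were given to mature miRNAs are not given in the sources used here. The labels do not say whether the replicates of a group came from separate cultures. If they did not, the p-values measure only the spread between libraries.

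The deposited mRNA table holds counts of 52459 named genes, and the deposited miRNA table holds counts of 1916 mature miRNAs. All values were whole numbers, and no 2 libraries of a group were copies: the lowest chi-square per degree of freedom between them was 3.39 for mRNA and 31.95 for miRNA, over features with a summed count of at least 20. Of the mRNA names 48108 were found in the gene name reference and 35095 in the RefSeq reference. At the end of the mRNA table are 2199 nameless lines with values in a single field, assigned here to the column of control 0 h replicate b. That column held 220180 counts on named genes, and those lines 15490. Over genes it correlated at 0.182 and 0.183 with the other replicates of its group, which correlated at 0.99 with each other. It gave Col2a1 10 counts against 1603729 and 998568. The column was therefore left out, so that 38 mRNA libraries and 2 mRNA controls at 0 h were analysed. This was decided after the values were seen, and the counts with all 39 libraries are given as an alternative.

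Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3, and the data.table package at 1.17.8) by the quasi-likelihood F test, with TMM scaling and the default low-count filter by group (filterByExpr), in 1 fit per assay with a coefficient for each group and no covariate. Features with a Benjamini-Hochberg adjusted p under 0.05 were called. The filter left 18857 genes and 588 miRNAs, which held 99.905% and 99.992% of the counts. TMM factors ranged from 0.864 to 1.12 for mRNA and from 0.677 to 1.12 for miRNA, and the common biological coefficient of variation was 8.26% and 19.3%. Each cytokine was compared with the control of the same time, IL-1beta with TNF-alpha at each time, and control at 72 h with control at 0 h. Whether an effect differed between the 4 times was tested by the interaction of treatment and time. The tests, comparisons, lists and alternatives were chosen before the data were examined, except where the text says otherwise. Tables were read and figures drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

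Lists of 25 kinds of genes and 8 kinds of miRNAs were written from general knowledge, and the 24 and 7 with enough members past the filter were tested with camera on voom values (2-sided, preset inter-gene correlation 0.01), adjusted over the lists and comparisons of each assay. They cover inflammation, cartilage and fibrous matrix, proteases, chondrocyte regulators and hypertrophy, signalling and stress responses, the cell cycle and clock, miRNA machinery and host genes, and markers of other cell types. For miRNAs they cover inflammation, cartilage, other cell types, pluripotency, the Dlk1-Dio3 locus and the let-7, miR-17-92 and miR-29 families. Of the list members 1 gene was not in the mRNA table. With an estimated correlation 50 of the 131 called results of the 312 mRNA tests and 10 of the 16 of the 91 miRNA tests kept their call, and fry and a replicate block were run as well. The report gives a selection of the called lists, with the second p where the call was lost.

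Genes were named by a rule: for each comparison and direction the 5 called genes of largest absolute log2 fold change, with mean CPM of at least 1 and all libraries of the groups apart, without symbols of the form Gm plus number, ending in Rik or containing -ps. Added were 2 to 4 members of each list with the smallest p, and members named for contrast. All called miRNAs were named where 12 or fewer were called, and otherwise the 6 largest in each direction with mean CPM of at least 10, of which some are given here. Host genes of named miRNAs were added. The 10 predicted genes of the library parting were chosen after their values were seen, as were the genes and miRNAs drawn in the figures.

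The alternatives were DESeq2 1.42.0 with its Wald test, its median-of-ratios factors in edgeR, library totals alone, no low-count filter, the replicate letter as a block, a fit on only the libraries compared, and leaving out each library in turn. Chosen after the data were seen were the fits with all 39 mRNA libraries, without the miRNA libraries IL-1beta 12 h b and TNF-alpha 72 h b, and on 1 side of the library parting. The similarity of the responses was set beside 10 simulated sets per time in which unchanged groups shared the same controls. The method was tested on simulated data in the layout of IL-1beta against control at 4 h. Of simulated changes of 0.5, 1 and 2 on the log2 scale it recovered 59.1%, 92.5% and 98.5% for mRNA, with 6 unchanged genes called of 17694, and 30%, 90% and 90% for miRNA, with 1 unchanged miRNA called. The miRNA pairs with host genes were written after the data came, from general knowledge. Seed sites of miRNAs in 3' untranslated regions were not analysed here, so no link between a miRNA and its targets is reported.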

Results

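The libraries came from mouse cartilage engineered in culture from induced pluripotent stem cells and exposed to 1 ng/mL interleukin-1 beta (IL-1beta) or 20 ng/mL tumor necrosis factor alpha (TNF-alpha), both inflammatory cytokines. Of the 78 libraries 39 measured mRNA and 39 measured small RNA (miRNA). Each assay held 13 groups of 3 libraries: untreated controls at 0, 4, 12, 24 and 72 h, and each cytokine at 4, 12, 24 and 72 h. The series title names the question as how miRNAs and mRNAs act together in this inflammatory response. The 38 mRNA libraries analysed held 11163263 to 68655350 counts, and the 39 miRNA libraries held 4653364 to 17994498 counts. The remaining mRNA column, replicate b of control at 0 h, correlated with the other libraries at 0.189 or less and was left out. Features are named by the gene symbols and mature miRNA names of the tables, which carry no positions. Values written with ± are log2 fold changes with their standard error from edgeR, with 3 libraries in each group (2 at 0 h for mRNA). Unless an exception is named, all libraries of the higher group lay above all libraries of the lower group for each feature given with such a value. For features with 3 or fewer counts in a group, the ratio of normalised counts is given with its 95% counting interval, or a lower bound where there was no count, and these cover counting error only. The largest changes are meant within the naming rule given with the methods. Where leaving out 1 library moved a log2 fold change by over 1.5-fold, the value without it stands at the end of the paragraph, on the log2 scale also for ratios. Libraries are named there by group and replicate letter. Where a call was lost without 1 library, the log2 fold changes over all fits that left out 1 library of the comparison stand in brackets as a range. For gene lists, a called list given with a single p also passed with an estimated correlation between its genes.

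Both cytokines changed many genes at every time. With IL-1beta against control, 2920 genes rose and 3239 fell at 4 h, 2737 and 2836 at 12 h, 3203 and 2939 at 24 h, and 3630 and 3706 at 72 h, of 18857 tested. With TNF-alpha, 2052 rose and 1996 fell at 4 h, 2750 and 2611 at 12 h, 2488 and 2235 at 24 h, and 3348 and 3442 at 72 h. At least 2-fold changes were fewer: 1165 genes rose and 1213 fell by that much with IL-1beta at 72 h, against 886 and 662 with TNF-alpha. The 3 treated and 3 control libraries did not overlap for 42.2%, 39.1%, 46.2% and 51.2% of genes with IL-1beta at 4, 12, 24 and 72 h, and for 38.9%, 36.2%, 40.7% and 45.5% with TNF-alpha, where chance gives 10%. Scaling by library totals alone moved the median change of all genes by -0.101 with IL-1beta at 4 h and by 0.109 with TNF-alpha at 72 h. Under it the share of called genes that rose went from 47.4% to 28.4% with IL-1beta at 4 h, from 50.7% to 40.5% with TNF-alpha at 4 h and from 49.3% to 67.1% with TNF-alpha at 72 h. A set of 10 predicted genes, chosen after their values were seen, parted the libraries of control 0 h, control 4 h and IL-1beta 4 h from all others, and this parting runs through the TNF-alpha comparison at 4 h. That comparison alone cannot tell a library batch from TNF-alpha, though Il6 and Slc7a11 lay above all later controls too. Against the 12 h controls, on the same side but later, TNF-alpha at 4 h gave 4936 called genes. With the left-out column included, IL-1beta gave 2848, 2722, 3029 and 4284 genes at the 4 times and TNF-alpha 1584, 2331, 2038 and 3330. Mitochondrial genes took 0.384% to 0.424% of counts with IL-1beta and 0.42% to 0.4215% with TNF-alpha at 12 h, against 0.237% to 0.351% in the controls. The shares were 0.551% to 0.618% and 0.55% to 0.564% against 0.355% to 0.384% at 24 h, and 0.574% to 0.594% and 0.568% to 0.61% against 0.384% to 0.443% at 72 h.

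**Figure D1:**
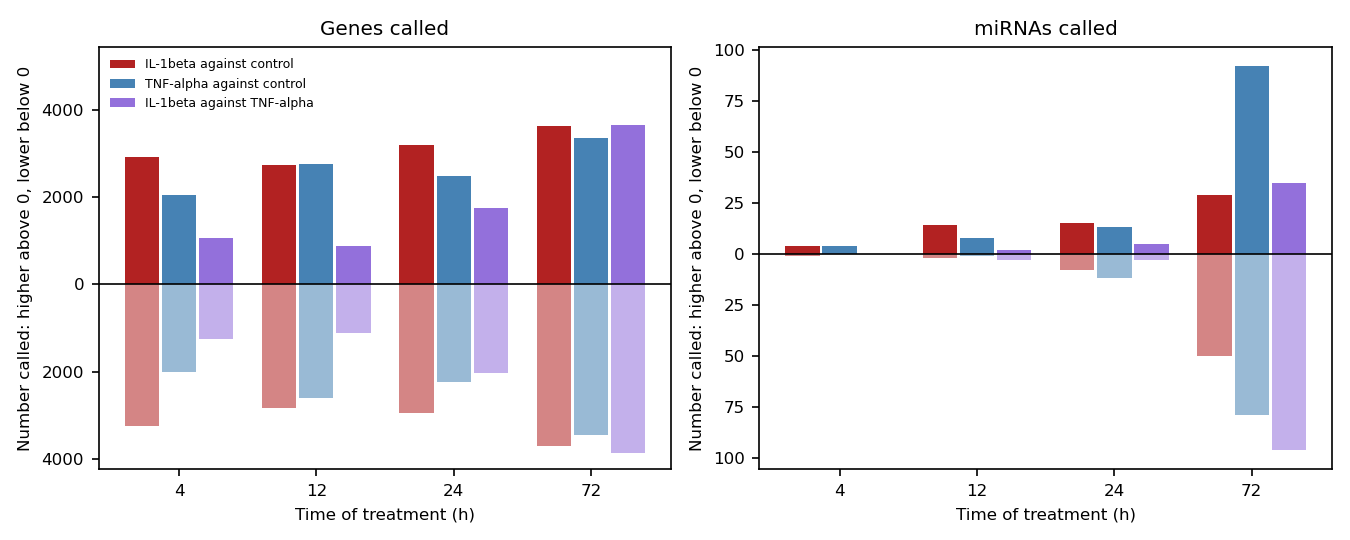
Number of genes (left) and mature miRNAs (right) called by edgeR at a false discovery rate of 0.05 in each comparison, against the time of treatment in h. Bars above 0 count features higher with the first-named treatment and paler bars below 0 count features lower, up to 3656 and 3856 genes for IL-1beta against TNF-alpha at 72 h.

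IL-1beta raised the inflammatory genes of the cartilage from 4 h on. Of 24 tested components and targets of NF-kappaB, a transcription factor family of inflammation, 23 rose and 0 fell (23 and 0 adjusted over the list alone) at 4 h (camera adjusted p = 3.63e-32). Leading were Icam1 (3.64 ± 0.10), Sod2 (2.47 ± 0.0904), Nfkbia (2.34 ± 0.0923) and Nfkb1 (1.43 ± 0.0569). At 72 h 21 rose and 0 fell (21 and 0 adjusted over the list alone), camera adjusted p = 1.22e-16. Of 17 tested chemokines, which attract leukocytes, 12 rose and 0 fell (14 and 0 adjusted over the list alone) at 4 h (camera adjusted p = 1.61e-10). Leading were Cxcl1 (5.14 ± 0.18), Cxcl2 (6.37 ± 0.27) and Ccl2 (4.62 ± 0.20). At 72 h 13 rose and 0 fell (13 and 0 adjusted over the list alone), with Cxcl1 (5.90 ± 0.19) and Ccl2 (4.22 ± 0.20) first (camera adjusted p = 5.81e-08, and adjusted p = 0.0568 with an estimated correlation). Of 19 tested cytokines and inflammatory mediators, 14 rose and 1 fell (14 and 1 adjusted over the list alone) at 4 h (camera adjusted p = 4.37e-13), among them Ptges (3.31 ± 0.10), Il6 (5.82 ± 0.22), Nos2 (5.55 ± 0.23) and Lif (5.61 ± 0.24). Ptges makes prostaglandin E2 and Nos2 makes nitric oxide. At 72 h 11 rose and 3 fell (11 and 3 adjusted over the list alone) of that list, camera adjusted p = 2.5e-06, led by complement C3 (4.97 ± 0.17), Nos2 (6.12 ± 0.28) and serum amyloid Saa3 (8.95 ± 0.45).

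The largest rises with IL-1beta at 4 h were in Ccl20 (7.85 ± 0.52), Slc6a14 (6.91 ± 0.39) and Serpinb2 (6.56 ± 0.37), beside the inflammasome gene Nlrp3 at 328-fold (counting interval 90.3 to 2710) and Slc26a9 at 452-fold (counting interval 80.7 to 17900) the control level. At 12 h they were in Csf3 (6.99 ± 0.48), Ch25h (6.73 ± 0.36), Slc6a14 (6.52 ± 0.49) and Ccl5 (6.32 ± 0.45), with Cxcl3 at 134-fold (counting interval 45.4 to 653). At 24 h Ch25h (7.18 ± 0.35), Mmp9 (6.75 ± 0.36), Cybb (6.74 ± 0.59), Ccl5 (6.39 ± 0.39) and Ccl20 (6.36 ± 0.66) led. At 72 h the acute-phase genes led: Saa3 went from 32 ± 8.31 to 15750 ± 2560 CPM (counts scaled to library size; SD, n = 3), followed by Saa2 (8.34 ± 0.44), Vnn3 (8.18 ± 0.23), Mmp9 (7.95 ± 0.30) and Saa1 (7.75 ± 0.40). The largest falls at 4 h were in Fam198a (-2.69 ± 0.38), AI593442 (-2.64 ± 0.27), Zfp648 (-2.60 ± 0.26), Id4 (-2.55 ± 0.28) and the protease gene Adamts15 (-2.49 ± 0.36). At 12 h they were in Cldn2 (-3.49 ± 0.51), Kcne3 (-3.49 ± 0.45), Ppp1r3g (-3.41 ± 0.39), Adra2c (-3.38 ± 0.42) and Mgarp (-3.21 ± 0.25). At 24 h they were in Caln1 (-4.40 ± 0.44), Fam198a (-3.82 ± 0.36), Cmtm5 (-3.54 ± 0.26), Zfp648 (-3.52 ± 0.30) and Tnni2 (-3.39 ± 0.39). The largest edgeR adjusted p among the genes of this paragraph given with a standard error was 1.36e-06, for Cldn2. Slc6a14 went to 6.125 without control 4 h a and 8.015 without control 4 h b, Slc26a9 went from 8.21 to 9.58 without control 4 h a and Cxcl3 went from 6.93 to 7.86 without control 12 h c. Ccl5 went to 7.05 without control 24 h a, Ccl20 went to 6.96 without control 24 h b and Saa2 went to 9.08 without control 72 h c. Kcne3 went to -4.20 without IL-1beta 12 h c, Ppp1r3g went to -4.00 without IL-1beta 12 h b and Caln1 went to -5.09 without IL-1beta 24 h b.

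Cartilage matrix genes fell with IL-1beta as proteases rose. Of 24 tested matrix genes, 2 rose and 12 fell (2 and 12 adjusted over the list alone) at 12 h (camera adjusted p = 0.00376, and adjusted p = 0.49 with an estimated correlation). At 24 h 1 rose and 21 fell (1 and 21 adjusted over the list alone), camera adjusted p = 1.22e-16, with a median of -1.21. At 72 h 1 rose and 22 fell (1 and 22 adjusted over the list alone), camera adjusted p = 1.96e-23, with a median of -2.48, led by Matn3 (-4.90 ± 0.19), Frzb (-3.33 ± 0.14), Acan (-3.05 ± 0.14) and Fmod (-2.38 ± 0.11). Acan encodes aggrecan, the main cartilage proteoglycan. Col2a1, the main cartilage collagen gene, took 0.971% ± 0.0648 of all counts with IL-1beta at 72 h against 5.61% ± 0.696 in the control (SD, n = 3). The largest falls with IL-1beta at 72 h were in Tnni2 (-6.20 ± 0.35), Matn1 (-5.78 ± 0.32), Col10a1 (-5.27 ± 0.42), Omd (-4.99 ± 0.29) and Matn3, with 8.89e-13 for Col10a1 as the largest edgeR adjusted p among these 5. Of 21 tested matrix-degrading proteases, 15 rose and 2 fell (16 and 2 adjusted over the list alone) at 72 h (camera adjusted p = 7.81e-10). Leading were Mmp3 (6.12 ± 0.16), Mmp13 (4.92 ± 0.16) and Mmp9 (7.95 ± 0.30). At 4 h 11 rose and 2 fell (11 and 3 adjusted over the list alone), led by Mmp3 (3.02 ± 0.14) and Plau (1.76 ± 0.12) (camera adjusted p = 1.47e-05, and adjusted p = 0.183 with an estimated correlation). Tnni2 went to -6.82 without IL-1beta 72 h c.

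Regulators of chondrocyte identity moved with the matrix under IL-1beta. Of 16 tested, 1 rose and 11 fell (1 and 12 adjusted over the list alone) at 24 h (camera adjusted p = 1.7e-07). Leading were Fgfr3 (-2.06 ± 0.14), Wwp2 (-1.27 ± 0.09), Runx1 (1.10 ± 0.0861) and Sox6 (-0.75 ± 0.0601). At 72 h 1 rose and 13 fell (1 and 13 adjusted over the list alone), with Runx1 (1.93 ± 0.0884), Gdf5 (-1.96 ± 0.12) and Sox9 (-1.48 ± 0.10) first (camera adjusted p = 8.3e-06, and adjusted p = 0.0606 with an estimated correlation). Sox9 is the master transcription factor of cartilage. Of 14 tested genes of chondrocyte hypertrophy and mineralization, 3 rose and 8 fell (3 and 8 adjusted over the list alone) at 72 h (camera adjusted p = 0.00947, and adjusted p = 0.0773 with an estimated correlation), with Mef2c (-1.65 ± 0.0845) and Dmp1 (-4.75 ± 0.34) first. Of 18 tested genes of TGF-beta and BMP signalling, 3 rose and 8 fell (3 and 8 adjusted over the list alone) at 24 h (camera adjusted p = 0.0159, and adjusted p = 0.203 with an estimated correlation), and Bmp2 (1.84 ± 0.15) rose while its antagonists Grem1 (-1.18 ± 0.10) and Nog (-1.55 ± 0.17) fell. Of 15 tested fibroblast genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone) at 72 h (camera adjusted p = 0.0204, and adjusted p = 0.336 with an estimated correlation). Leading were Lum (1.98 ± 0.11) and Pdgfra (1.16 ± 0.12). Of 15 tested host genes of miRNAs, 2 rose and 9 fell (2 and 9 adjusted over the list alone) at 72 h (camera adjusted p = 2.09e-06). The imprinted noncoding transcripts Rian (-3.07 ± 0.0703), Mirg (-2.85 ± 0.11), Meg3 (-3.06 ± 0.14) and H19 (-2.59 ± 0.18) led those falls.

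Genes of hypoxia and glycolysis fell and then rose with IL-1beta. Of 16 tested, 1 rose and 14 fell (1 and 14 adjusted over the list alone) at 12 h (camera adjusted p = 4.82e-16). Leading were Pdk1 (-2.20 ± 0.0833), Egln3 (-2.31 ± 0.12) and Bnip3 (-2.18 ± 0.12). At 24 h 1 rose and 14 fell (1 and 14 adjusted over the list alone), camera adjusted p = 5.57e-10. At 72 h 11 rose and 0 fell (13 and 0 adjusted over the list alone), led by Ldha (0.92 ± 0.0771) and Pfkfb3 (1.00 ± 0.0913) (camera adjusted p = 1.56e-06, and adjusted p = 0.132 with an estimated correlation). Of 13 tested genes of the oxidative stress response, 10 rose and 1 fell (10 and 1 adjusted over the list alone) at 12 h (camera adjusted p = 5.44e-19). Leading were targets of the transcription factor NRF2, Srxn1 (2.87 ± 0.0751), Slc7a11 (4.47 ± 0.12), Txnrd1 (2.32 ± 0.0695) and Hmox1 (3.66 ± 0.11). At 72 h 7 rose and 2 fell (7 and 2 adjusted over the list alone) (camera adjusted p = 0.0324, and adjusted p = 0.455 with an estimated correlation), led by the metallothionein Mt2 (2.53 ± 0.23). Of 15 tested immediate early genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone) at 4 h (camera adjusted p = 1.43e-06, and adjusted p = 0.111 with an estimated correlation). Leading were Junb (1.02 ± 0.0881) and Fosl2 (0.97 ± 0.0843). Of 26 tested interferon response genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone) at 4 h (camera adjusted p = 0.000167, and 0.566 with an estimated correlation). Gbp2 (3.83 ± 0.25) and Gbp5 (3.96 ± 0.33) led, and rose by 2.77 and 3.93 at 24 h. At 12 h the list did not pass (3 rose and 2 fell, also over the list alone, camera adjusted p = 0.822).

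**Figure D2:**
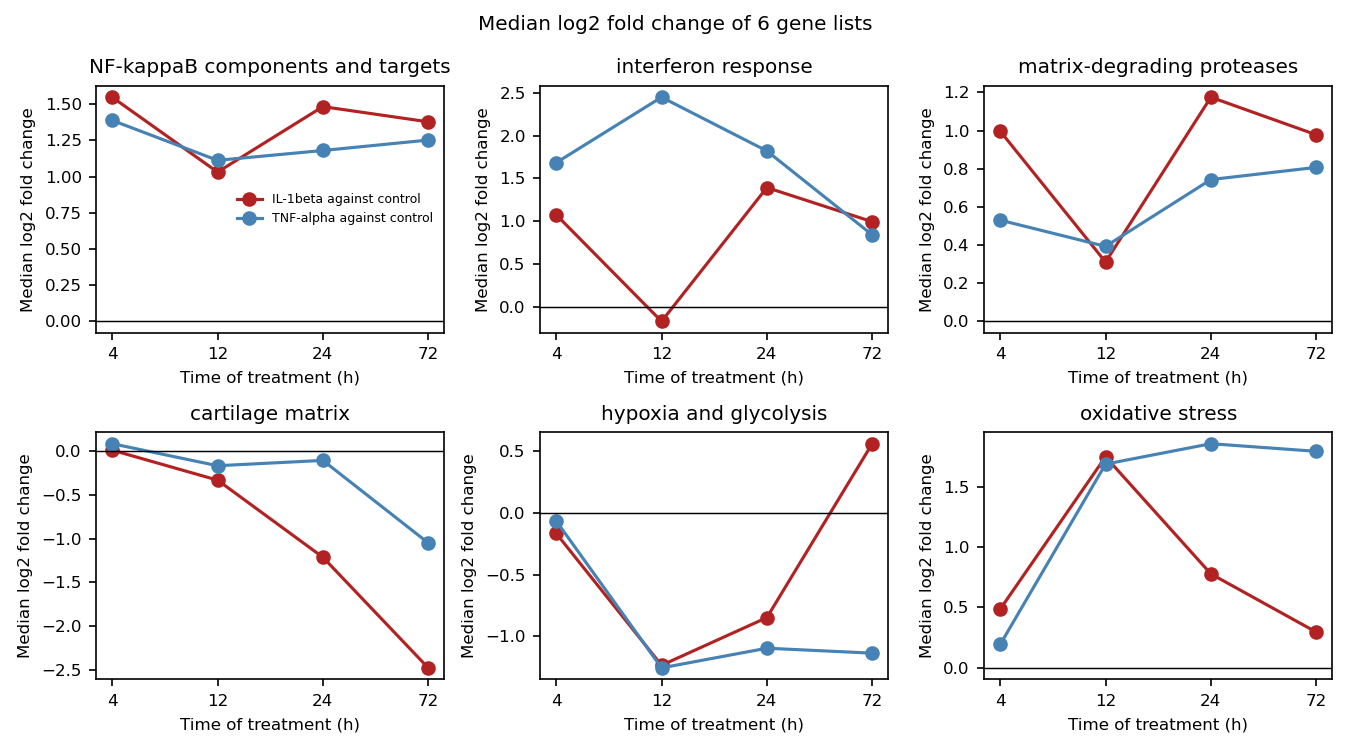
Median log2 fold change of the tested members of 6 gene lists fixed beforehand, against the time of treatment in h (evenly spaced), for each cytokine against its control. The cartilage matrix median reached -2.48 with IL-1beta and -1.05 with TNF-alpha at 72 h, and the hypoxia median was 0.56 with IL-1beta and -1.14 with TNF-alpha.

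TNF-alpha raised the same classes of inflammatory genes. Of the NF-kappaB list, 21 rose and 0 fell (21 and 0 adjusted over the list alone) at 4 h (camera adjusted p = 1.89e-38), led by Icam1 (3.93 ± 0.11), Nfkbia (2.67 ± 0.0934), Tnfaip2 (3.43 ± 0.14) and Tnfaip3 (3.32 ± 0.14), and 19 rose and 0 fell (19 and 0 adjusted over the list alone) at 72 h (camera adjusted p = 8.75e-17). Of the chemokines, 15 rose and 0 fell (15 and 1 adjusted over the list alone) at 4 h (camera adjusted p = 2.65e-18). Leading were Cxcl2 (6.93 ± 0.27), Ccl2 (5.29 ± 0.20) and Cxcl1 (3.57 ± 0.17). At 72 h 15 rose and 0 fell (15 and 0 adjusted over the list alone) (camera adjusted p = 1.61e-10). Leading were Ccl2 (5.55 ± 0.21), Ccl7 (4.21 ± 0.18) and Ccl5 (8.15 ± 0.37). Of the cytokines and mediators, 12 rose and 2 fell (13 and 2 adjusted over the list alone) at 4 h (camera adjusted p = 2.81e-12). Leading were Ptges (3.32 ± 0.10), Csf1 (3.74 ± 0.12) and Lif (5.59 ± 0.24). At 72 h 11 rose and 3 fell (11 and 3 adjusted over the list alone) (camera adjusted p = 2.53e-06), with Ptges (3.31 ± 0.10) and Csf1 (3.63 ± 0.12) first. Of the interferon response genes, 24 rose and 0 fell (25 and 0 adjusted over the list alone) at 12 h (camera adjusted p = 5.84e-11, and adjusted p = 0.253 with an estimated correlation). Leading were Gbp2 (4.45 ± 0.27), Irf1 (2.45 ± 0.18) and Gbp5 (4.61 ± 0.36). Of the immediate early genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone) at 4 h (camera adjusted p = 2.35e-08, and adjusted p = 0.0597 with an estimated correlation).

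The largest rises with TNF-alpha at 4 h were in Ccl20 (9.11 ± 0.50), Pdgfb (8.14 ± 0.55) and Cxcl10 (7.78 ± 0.83), with Nlrp3 at 1420-fold (counting interval 392 to 11700) and Tnf itself at 276-fold (counting interval 93.4 to 1340) the control level. Ccl5 led at 12 h (8.87 ± 0.40) and 24 h (9.11 ± 0.37), when the adhesion molecule gene Madcam1 (7.57 ± 0.44 and 8.01 ± 0.40) and Ch25h (7.72 ± 0.34 and 7.98 ± 0.34) followed. Cxcl3 was at 389-fold (counting interval 133 to 1890) and Pdgfb at 124-fold (counting interval 41.9 to 602) the control level at 12 h. At 24 h Cybb (7.51 ± 0.57) rose too, and Nlrp3 was at 312-fold (counting interval 55.7 to 12400). At 72 h no counts of Madcam1, U90926 or Mmp1b were found in the 3 controls, and the treated level was at least 159-fold, at least 141-fold and at least 72.2-fold higher, taking 3 counts over the control group as the floor. Clec4e was at 867-fold (counting interval 240 to 7170) and Ccl5 rose by 8.15 ± 0.37. The largest falls at 4 h were in Adra2c (-2.97 ± 0.39), Olfm4 (-2.45 ± 0.46), Kcne3 (-2.35 ± 0.29), Cbln1 (-2.31 ± 0.36) and Cavin2 (-2.15 ± 0.40). At 12 h Apln (-4.08 ± 0.22), Gpr35 (-3.73 ± 0.26), Ankrd37 (-3.57 ± 0.31), Mgarp (-3.29 ± 0.24) and Ppp1r3g (-3.18 ± 0.35) fell most. At 24 h Gpr35 (-4.69 ± 0.28), Mgarp (-3.75 ± 0.23), Apln (-3.69 ± 0.21), Ppp1r3g (-3.64 ± 0.35) and AC153541.3 (-3.53 ± 0.37) did. At 72 h Cidec (-6.45 ± 0.88), Adipoq (-6.23 ± 0.75), Nell2 (-5.87 ± 0.49), Car9 (-4.77 ± 0.25) and Ptn (-4.72 ± 0.52) fell most, and the largest edgeR adjusted p of this paragraph was 0.000126, for Olfm4 at 4 h. Cxcl10 went to 8.54 without control 4 h c, Ccl5 went to 9.77 without control 24 h a and Cxcl3 went from 8.44 to 9.38 without control 12 h c. Pdgfb went from 6.87 to 7.80 without control 12 h b and 6.12 without TNF-alpha 12 h b, Nlrp3 went from 7.90 to 9.94 without control 24 h b and Clec4e went from 9.53 to 8.94 without control 72 h b and 12.36 without control 72 h c. Cbln1 went to -2.93 without TNF-alpha 4 h b, Cidec went to -9.68 without TNF-alpha 72 h a and -5.69 without TNF-alpha 72 h b and Adipoq went to -8.04 without TNF-alpha 72 h a and -5.46 without TNF-alpha 72 h b. Nell2 went to -6.71 without TNF-alpha 72 h b.

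With TNF-alpha the cartilage matrix list passed at 72 h. At 12 h 4 rose and 7 fell (4 and 9 adjusted over the list alone) of its 24 genes and at 24 h 4 rose and 5 fell (5 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.218 and 0.53). At 72 h 1 rose and 20 fell (1 and 21 adjusted over the list alone) (camera adjusted p = 1.97e-10, and adjusted p = 0.0907 with an estimated correlation), led by Frzb (-1.74 ± 0.13) and Hapln1 (-1.22 ± 0.11), while the lubricin gene Prg4 rose (1.78 ± 0.18). Col2a1 took 5.87% ± 1.21 of all counts at 12 h against 8.56% ± 0.757 in the control and 5.34% ± 1.13 with IL-1beta (SD, n = 3). It took 3.53% ± 0.696 against 5.28% ± 0.341 in the control at 24 h, and 2.38% ± 0.348 at 72 h. Proteases rose at 4 h, when 11 rose and 1 fell (12 and 2 adjusted over the list alone) (camera adjusted p = 1.22e-07, and adjusted p = 0.0942 with an estimated correlation). At 72 h 13 rose and 3 fell (13 and 3 adjusted over the list alone) (camera adjusted p = 1.32e-06, and adjusted p = 0.129 with an estimated correlation). Leading were Mmp3 (5.71 ± 0.15), Mmp9 (7.01 ± 0.31) and Mmp12 (5.84 ± 0.28). Of the chondrogenic regulators, 1 rose and 11 fell (1 and 11 adjusted over the list alone) at 72 h (camera adjusted p = 7.4e-07). Leading were Sox6 (-0.84 ± 0.0603), Sox9 (-1.27 ± 0.10) and Gdf5 (-1.31 ± 0.11). Of the hypertrophy genes, 2 rose and 8 fell (2 and 8 adjusted over the list alone) at 72 h (camera adjusted p = 0.00881, and adjusted p = 0.0773 with an estimated correlation). Of the fibroblast genes, 2 rose and 8 fell (2 and 8 adjusted over the list alone) at 72 h (camera adjusted p = 0.00779, and adjusted p = 0.249 with an estimated correlation), among them the collagen genes Col1a1 (-2.35 ± 0.18) and Col1a2 (-1.37 ± 0.12). Of the host genes, 4 rose and 10 fell (4 and 10 adjusted over the list alone) at 72 h (camera adjusted p = 0.00148, and adjusted p = 0.122 with an estimated correlation), led by Rian (-1.0 ± 0.0648) and Wwp2 (-1.02 ± 0.0896), the host of miR-140.

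Under TNF-alpha the fall of hypoxia and glycolysis genes lasted. Of 16, 2 rose and 14 fell (2 and 14 adjusted over the list alone) at 12 h (camera adjusted p = 2.94e-18). Leading were Pdk1 (-2.10 ± 0.0816), Pfkfb3 (-2.07 ± 0.10) and Bnip3 (-2.37 ± 0.12). At 72 h 0 rose and 14 fell (0 and 14 adjusted over the list alone) (camera adjusted p = 7.83e-14). Leading were Bnip3 (-2.14 ± 0.10), Pdk1 (-1.52 ± 0.0776) and Car9 (-4.77 ± 0.25). Oxidative stress genes stayed high: 10 rose and 1 fell (10 and 1 adjusted over the list alone) at 12 h (camera adjusted p = 1.62e-18), and 12 rose and 1 fell (12 and 1 adjusted over the list alone) at 72 h (camera adjusted p = 1.57e-15). Leading were Slc7a11 (4.62 ± 0.13), Txnrd1 (1.96 ± 0.069) and Gclm (2.22 ± 0.0888). Of 7 tested adipocyte markers, 0 rose and 6 fell (0 and 7 adjusted over the list alone) at 24 h (camera adjusted p = 0.000205, and adjusted p = 0.143 with an estimated correlation) and 0 rose and 6 fell (0 and 6 adjusted over the list alone) at 72 h (camera adjusted p = 0.0106, and adjusted p = 0.354 with an estimated correlation), where the fat cell hormone Adipoq went from 5.8 ± 2.31 to 0.0851 ± 0.113 CPM (SD, n = 3). Markers of other cell types were tested as well. Of 7 tested leukocyte markers, 3 rose and 2 fell (3 and 2 adjusted over the list alone) with TNF-alpha at 72 h and 2 rose and 1 fell (2 and 1 adjusted over the list alone) with IL-1beta, and neither passed as a list (camera adjusted p = 0.463 and 0.336). The endothelial (2 tested), epithelial (4), muscle (3) and neural (8) lists and the 12 genes of the miRNA machinery passed for neither cytokine at any time, with camera adjusted p from 0.123 up. Of the pluripotency markers only Sox2 was tested, and it fell with IL-1beta at 4 h (-0.58 ± 0.17) and 12 h (-0.70 ± 0.21), with edgeR adjusted p at 4 h for Sox2 (-0.30 to -0.69), 0.0505 without control 4 h a and 0.273 without IL-1beta 4 h b, and at 12 h for Sox2 (-0.50 to -0.79), 0.126 without control 12 h a.

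Cell cycle genes fell with IL-1beta. Of 21 tested, 1 rose and 11 fell (1 and 12 adjusted over the list alone) at 12 h (camera adjusted p = 0.00467, and adjusted p = 0.491 with an estimated correlation). Later 1 rose and 14 fell (1 and 14 adjusted over the list alone) at 72 h (camera adjusted p = 5.82e-05, and adjusted p = 0.314 with an estimated correlation). Leading at 72 h were the DNA replication genes Mcm6 (-1.05 ± 0.0721) and Mcm3 (-0.91 ± 0.0858). With TNF-alpha 0 rose and 8 fell (1 and 10 adjusted over the list alone) at 12 h (camera adjusted p = 0.00618, and adjusted p = 0.504 with an estimated correlation). At 72 h 0 rose and 6 fell (0 and 5 adjusted over the list alone) and the list did not pass (camera adjusted p = 0.0599). Against control at 0 h the list was lower in the 72 h control as well, where 0 rose and 14 fell (0 and 15 adjusted over the list alone) (camera adjusted p = 4.06e-06, and adjusted p = 0.236 with an estimated correlation). Of 17 tested circadian clock genes, 1 rose and 10 fell (1 and 11 adjusted over the list alone) with IL-1beta at 12 h (camera adjusted p = 0.000399, and adjusted p = 0.128 with an estimated correlation). With TNF-alpha 0 rose and 10 fell (0 and 12 adjusted over the list alone) at 12 h (camera adjusted p = 1.03e-05, and adjusted p = 0.0538 with an estimated correlation). The clock genes Per3 (-0.73 ± 0.0763) and Dbp (-0.89 ± 0.10) led with TNF-alpha. Of 15 tested genes of the unfolded protein response, 9 rose and 1 fell (9 and 3 adjusted over the list alone) with TNF-alpha at 12 h (camera adjusted p = 0.00163, and adjusted p = 0.23 with an estimated correlation), led by the endoplasmic reticulum chaperone gene Hspa5 (0.62 ± 0.0574). With IL-1beta 1 rose and 8 fell (1 and 8 adjusted over the list alone) at 72 h (camera adjusted p = 0.0217, and adjusted p = 0.404 with an estimated correlation). Leading were Chac1 (-1.87 ± 0.16) and Trib3 (-1.21 ± 0.12).

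**Figure D3:**
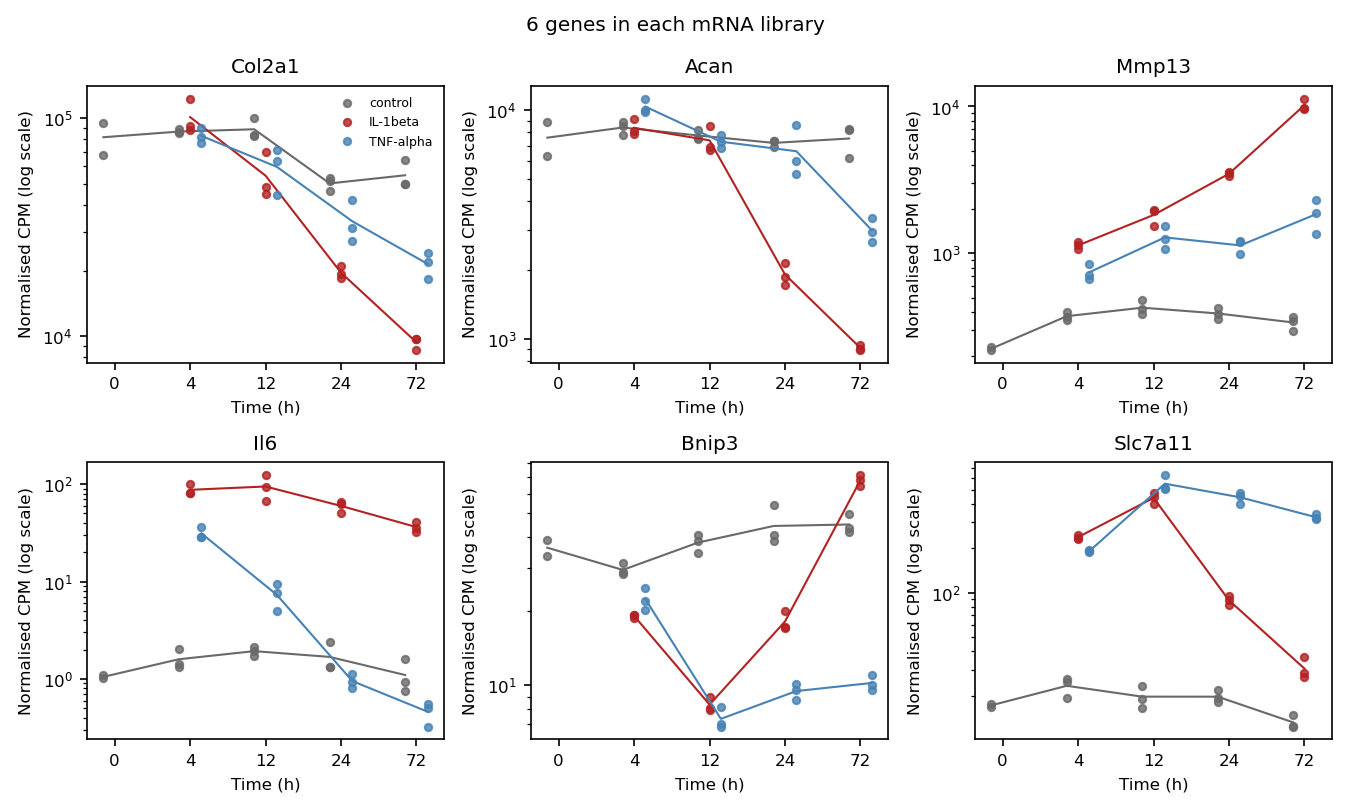
Normalised CPM (log scale) of 6 genes in each mRNA library against time in h (evenly spaced); points are libraries, shifted sideways by treatment, and lines join group means. Acan with IL-1beta at 72 h and Bnip3 with TNF-alpha at 12 to 72 h lie below every control library of the same time, and Il6 with IL-1beta lies above every control library at each time.

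The cytokines were also compared directly with each other. The count was highest at 72 h: 1076 genes were higher and 1256 lower with IL-1beta at 4 h, 887 and 1108 at 12 h, 1756 and 2034 at 24 h, and 3656 and 3856 at 72 h. With only the libraries compared 1549 were called at 4 h and 908 at 12 h, and with the left-out column included 685, 639, 1865 and 4342 at the 4 times. Il6 was higher with IL-1beta by 1.495 ± 0.17 at 4 h, 3.69 ± 0.19 at 12 h, 5.98 ± 0.24 at 24 h and 6.34 ± 0.28 at 72 h. So were Saa2 (4.87 ± 0.45 at 4 h, 8.21 ± 0.41 at 72 h), Saa1 (3.80 ± 0.43 and 6.997 ± 0.36) and Vnn3 (3.66 ± 0.28 at 12 h, 9.18 ± 0.24 at 72 h), and at 72 h Wfdc21 (8.21 ± 0.38) and Olfm4 (7.37 ± 0.38). Slc6a14 was higher with IL-1beta by 4.84 ± 0.37 at 4 h, and its level was 227-fold (counting interval 62.3 to 1880) that with TNF-alpha at 12 h and 86.9-fold (counting interval 29.4 to 424) at 24 h. Higher with TNF-alpha were Pdgfb (-3.08 ± 0.35), Tnfsf4 (-2.90 ± 0.32) and Cd247 (-2.48 ± 0.33) at 4 h, and Clec4e (-5.05 ± 0.32 and -7.61 ± 0.31), Madcam1 (-4.72 ± 0.26 and -5.91 ± 0.41), Csf1 (-2.93 ± 0.12 and -3.63 ± 0.12) and Traf1 (-3.36 ± 0.17 and -4.82 ± 0.21) at 24 and 72 h. Among proteases at 72 h Mmp13 was higher with IL-1beta (2.47 ± 0.14) and Mmp10 (-4.55 ± 0.27) and Mmp12 (-3.63 ± 0.23) lower. Under library totals the share higher with IL-1beta went from 46.1% to 27.2% at 4 h and from 48.7% to 34.9% at 72 h. The 4 h comparison runs through the parting of the libraries described above, and without TNF-alpha 4 h replicate a it gave 1431 called genes. Vnn3 went to 4.57 without TNF-alpha 12 h a, Olfm4 went to 8.43 without TNF-alpha 72 h b and Slc6a14 went from 7.66 to 10.64 without TNF-alpha 12 h a. Slc6a14 went from 6.235 to 7.05 without TNF-alpha 24 h c and Clec4e went to -8.30 without IL-1beta 72 h a.

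Gene groups parted between the cytokines. Of the interferon response genes 0 were higher and 26 lower (0 and 26 adjusted over the list alone) with IL-1beta at 12 h, camera adjusted p = 5.44e-19, and adjusted p = 0.104 with an estimated correlation, where Rsad2 (-5.33 ± 1.05), Mx1 (-4.94 ± 1.10), Cxcl10 (-4.76 ± 0.71), Cmpk2 (-4.62 ± 0.94) and Ifit1 (-4.05 ± 0.91) differed most. In the matrix list 0 were higher and 22 lower (1 and 23 adjusted over the list alone) with IL-1beta at 24 h, camera adjusted p = 3.55e-20. At 72 h 0 were higher and 23 lower (1 and 23 adjusted over the list alone), camera adjusted p = 1.21e-15, led by Matn3 (-4.53 ± 0.19) and Matn1 (-4.67 ± 0.32). Of the hypoxia and glycolysis genes 16 were higher and 0 lower (16 and 0 adjusted over the list alone) with IL-1beta at 72 h, camera adjusted p = 4.02e-18, led by Ldha (2.21 ± 0.08), Pdk1 (2.04 ± 0.0782) and Bnip3 (2.73 ± 0.10). Of the oxidative stress genes 3 were higher and 10 lower (3 and 10 adjusted over the list alone) at 72 h, camera adjusted p = 1.92e-07, led by Slc7a11 (-3.42 ± 0.12) and Gclm (-2.32 ± 0.089). Of the fibroblast genes 11 were higher and 1 lower (11 and 1 adjusted over the list alone) at 72 h, camera adjusted p = 1.03e-06, led by Col3a1 (2.21 ± 0.14), Postn (2.07 ± 0.14) and Col1a1 (2.09 ± 0.18). Of the adipocyte markers 7 were higher and 0 lower (7 and 0 adjusted over the list alone) with IL-1beta at 72 h (camera adjusted p = 0.000356, and adjusted p = 0.161 with an estimated correlation). The neural list was lower at 24 h, where 0 were higher and 2 lower (0 and 4 adjusted over the list alone), camera adjusted p = 0.00894. In the leukocyte list 1 was higher and 0 lower (2 and 0 adjusted over the list alone) at 4 h, camera adjusted p = 0.0401, and adjusted p = 0.428 with an estimated correlation, the gene called over all genes being Cd14 (0.82 ± 0.10). Rsad2 went to -3.81 without TNF-alpha 12 h a, Mx1 went to -4.25 without IL-1beta 12 h b and Cmpk2 went to -5.60 without IL-1beta 12 h b and -3.02 without TNF-alpha 12 h a.

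Over all 18857 genes the changes with the cytokines correlated at r = 0.668 at 4 h, 0.729 at 12 h, 0.632 at 24 h and 0.466 at 72 h. Genes are not independent replicates, and both changes share the same 3 controls. In simulated sets without any effect the shared controls alone gave mean r of 0.370, 0.461, 0.567 and 0.547. The covariance, which does not shrink with added variance, was 0.275, 0.344, 0.288 and 0.294 against 0.0338, 0.0485, 0.0496 and 0.0499 in the simulated sets. At 4 h 1458 genes rose with both cytokines, where independent calls give 318, and 34 were called in opposite directions. At 72 h 1537 rose with both, 1804 fell with both and 705 were called in opposite directions.

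The size of the response differed between the 4 times for 7299 genes with IL-1beta and 3618 with TNF-alpha in the edgeR test of that difference, or 2994 and 739 with the left-out column included. With the 4 h effect left out, since the parting of the libraries runs through it, 1460 genes differed between 12, 24 and 72 h with TNF-alpha. Untreated cartilage changed as well: against control at 0 h, 3396 genes were higher and 3702 lower at 72 h, and 47.8% of the called genes were higher, or 62.0% under library totals. The 10 predicted genes part these groups too. Against the 12 h controls, a shorter span of time, 6994 genes were called at 72 h, while 4331 were called against 0 h with the left-out column included. Largest at 72 h were rises in the matrix genes Matn1 (5.84 ± 0.40), Omd (4.22 ± 0.33) and Ogn (3.96 ± 0.28), in Azgp1 (4.22 ± 0.31) and in Fam198a (4.04 ± 0.37). Falls were largest in Slc17a8 (-4.45 ± 0.50), Bmp8a (-4.45 ± 0.60), Fgfbp1 (-4.39 ± 0.29), the hepatic and intestinal transcription factor Hnf4a (-4.29 ± 0.44) and Cd38 (-4.04 ± 0.34). Of the immediate early genes 0 rose and 14 fell (0 and 15 adjusted over the list alone) (camera adjusted p = 4.98e-10). Of the matrix genes 9 rose and 8 fell (9 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.143). With only 2 libraries at 0 h, non-overlap is given by chance more often than with 3. Omd went to 4.97 without control 0 h a, Azgp1 went to 5.15 without control 0 h a and Fam198a went to 5.12 without control 0 h a.

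Few miRNAs changed early with IL-1beta, and more at 72 h. Of 588 tested, 4 rose and 1 fell at 4 h, 14 and 2 at 12 h, 15 and 8 at 24 h, and 29 and 50 at 72 h. At 4 h miR-222-5p (1.27 ± 0.14), miR-222-3p (0.85 ± 0.12), miR-92a-1-5p (1.43 ± 0.21) and miR-155-5p (0.52 ± 0.11) rose and miR-341-5p (-0.72 ± 0.18) fell. Some of these calls were lost when 1 library was left out. The edgeR adjusted p was, for miR-155-5p (0.43 to 0.63), 0.0501 without control 4 h a, 0.0914 without control 4 h c and 0.079 without IL-1beta 4 h c. For miR-341-5p (-0.49 to -0.87), 0.69 without control 4 h a, 0.0764 without control 4 h c, 0.168 without IL-1beta 4 h a and 0.284 without IL-1beta 4 h b. Without control 4 h replicate a, and under library totals, 3 miRNAs were called. Of 18 tested miRNAs known from inflammation, 7 rose and 0 fell (7 and 0 adjusted over the list alone) at 72 h (camera adjusted p = 7.57e-05). Their leaders miR-155-5p (1.55 ± 0.11), miR-146a-5p (3.03 ± 0.41), miR-222-3p (0.84 ± 0.12) and miR-21a-3p (0.98 ± 0.14) include miR-146a, a feedback inhibitor of NF-kappaB signalling. Also among the largest rises at 72 h were miR-146b-5p (1.93 ± 0.47), miR-802-5p (1.74 ± 0.19), miR-138-5p (1.56 ± 0.29) and miR-93-5p (1.00 ± 0.13). Of 26 tested miRNAs of the imprinted Dlk1-Dio3 locus, 0 rose and 14 fell (0 and 18 adjusted over the list alone) at 72 h (camera adjusted p = 4.97e-09). Leading were miR-409-3p (-0.97 ± 0.11), miR-134-5p (-0.98 ± 0.14), miR-543-3p (-1.36 ± 0.20) and miR-376b-3p (-1.39 ± 0.27). The largest falls at 72 h were in miR-485-3p (-1.72 ± 0.17), miR-370-3p (-1.43 ± 0.18), miR-709 (-1.40 ± 0.20), miR-376b-3p, miR-540-3p (-1.39 ± 0.17) and miR-543-3p. At 24 h miR-155-5p (1.00 ± 0.11), miR-222-3p (1.13 ± 0.12), miR-146a-5p (1.97 ± 0.39), miR-20a-5p (1.09 ± 0.17) and miR-802-5p (1.10 ± 0.19) rose, and miR-485-3p (-1.06 ± 0.17) and miR-709 (-0.96 ± 0.20) fell.

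The count of miRNAs at 12 h with IL-1beta moved with single libraries. Without IL-1beta 12 h replicate b 5 were called instead of 16, while without replicate c 33 were. Without control replicate a, b or c, 9, 10 or 8 were called. With only the libraries compared 0 passed in edgeR, where the fit of all libraries gave 16 and DESeq2 15, and under library totals 9 did. Among the largest rises were miR-146b-5p (2.24 ± 0.48), miR-221-5p (2.09 ± 0.53), miR-146a-5p (1.97 ± 0.39) and miR-20a-5p (0.64 ± 0.17), and miR-210-5p fell (-0.70 ± 0.20). Their edgeR adjusted p was, for miR-146b-5p (0.775 to 2.68), 0.687 without IL-1beta 12 h b. For miR-221-5p (0.46 to 2.52), 0.118 without control 12 h a, 0.128 without control 12 h b, 0.116 without control 12 h c and 0.997 without IL-1beta 12 h b. For miR-146a-5p (1.04 to 2.33), 0.22 without IL-1beta 12 h b. For miR-20a-5p (0.50 to 0.72), 0.306 without control 12 h a, 0.128 without control 12 h c, 0.0551 without IL-1beta 12 h a and 0.417 without IL-1beta 12 h b. For miR-210-5p (-0.47 to -0.97), 0.128 without control 12 h b, 0.176 without control 12 h c, 0.0581 without IL-1beta 12 h a and 0.489 without IL-1beta 12 h b. The rises of miR-335-3p (1.86 ± 0.30) and miR-222-3p (0.94 ± 0.12) passed whichever library was left out. At 24 h 15 were called without control 24 h replicate b or c, instead of 23. There miR-335-3p (1.14 ± 0.29) rose and miR-376b-3p (-1.22 ± 0.27), miR-665-3p (-0.93 ± 0.22), miR-370-3p (-0.68 ± 0.17) and miR-540-3p (-0.63 ± 0.17) fell, and each lost its call without some library. The adjusted p was, for miR-335-3p (1.08 to 1.29), 0.0659 without control 24 h a, 0.0688 without control 24 h b and 0.0607 without IL-1beta 24 h a. For miR-376b-3p (-1.02 to -1.48), 0.0558 without control 24 h a, 0.0564 without control 24 h b and 0.0577 without IL-1beta 24 h a. For miR-665-3p (-0.76 to -1.12), 0.103 without control 24 h c, 0.12 without IL-1beta 24 h a and 0.0916 without IL-1beta 24 h c. For miR-370-3p (-0.55 to -0.78), 0.0873 without control 24 h b, 0.145 without control 24 h c, 0.12 without IL-1beta 24 h a and 0.168 without IL-1beta 24 h c. For miR-540-3p (-0.56 to -0.67), 0.0637 without control 24 h a, 0.102 without control 24 h b, 0.106 without control 24 h c, 0.0905 without IL-1beta 24 h b and 0.12 without IL-1beta 24 h c. Of 10 tested miRNAs of the miR-17-92 cluster and its paralogues, 2 rose and 0 fell (3 and 0 adjusted over the list alone) at 24 h (camera adjusted p = 0.00252, and adjusted p = 0.0981 with an estimated correlation). Library totals moved the median of all miRNAs by -0.137 at 12 h and took the share that rose at 4 h from 80% to 100%. miR-146b-5p went to 0.775 without IL-1beta 12 h b, miR-221-5p went to 0.46 without IL-1beta 12 h b and miR-146a-5p went to 1.04 without IL-1beta 12 h b. miR-335-3p went to 1.09 without IL-1beta 12 h b.

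With TNF-alpha 4 miRNAs rose and 0 fell at 4 h, 8 and 1 at 12 h, 13 and 12 at 24 h, and 92 and 79 at 72 h. Without the filter 15 were called at 4 h. Without IL-1beta 12 h b and TNF-alpha 72 h b 9, 14 and 46 were called at 4, 12 and 24 h. The 4 at 4 h were miR-222-5p (1.57 ± 0.14), miR-155-5p (0.67 ± 0.11), miR-222-3p (0.72 ± 0.12) and miR-92a-1-5p (1.02 ± 0.21). The edgeR adjusted p was, for miR-92a-1-5p (0.85 to 1.13), 0.281 without control 4 h b. At 12 h miR-222-3p (1.01 ± 0.12), miR-222-5p (1.13 ± 0.13) and miR-155-5p (0.67 ± 0.11) rose and miR-210-5p, a strand of the hypoxia miRNA miR-210, fell (-1.25 ± 0.20). The other 5 called at 12 h were miR-92a-1-5p (1.03 ± 0.22), miR-6237 (2.02 ± 0.47), miR-193b-5p (0.89 ± 0.22), miR-147-3p (0.96 ± 0.24) and miR-335-3p (1.14 ± 0.29). Each lost its call without some library, with adjusted p for miR-92a-1-5p (0.97 to 1.11), 0.0579 without control 12 h c. For miR-6237 (0.34 to 2.45), 0.119 without control 12 h a, 0.072 without control 12 h b, 0.0511 without control 12 h c and 0.883 without TNF-alpha 12 h c. For miR-193b-5p (0.81 to 0.99), 0.145 without control 12 h b, 0.129 without control 12 h c, 0.0965 without TNF-alpha 12 h a and 0.1 without TNF-alpha 12 h b. For miR-147-3p (0.64 to 1.11), 0.235 without control 12 h a, 0.129 without control 12 h c and 0.384 without TNF-alpha 12 h c. For miR-335-3p (0.80 to 1.285), 0.158 without control 12 h a, 0.072 without control 12 h b, 0.173 without control 12 h c and 0.374 without TNF-alpha 12 h c. Without control 12 h replicate c 4 miRNAs were called. At 24 h miR-222-3p (1.46 ± 0.12), miR-222-5p (1.41 ± 0.14), miR-147-3p (1.52 ± 0.23) and miR-20a-5p (1.16 ± 0.17) rose, and miR-709 (-1.32 ± 0.20) and miR-210-5p (-1.03 ± 0.20) fell. Also called were rises of miR-221-5p (1.79 ± 0.52) and miR-146a-5p (1.39 ± 0.38) and falls of miR-5106 (-0.94 ± 0.22), miR-485-3p (-0.64 ± 0.16), miR-1957a (-0.59 ± 0.14) and miR-540-3p (-0.56 ± 0.16). Their adjusted p was, for miR-221-5p (1.575 to 1.95), 0.146 without control 24 h a, 0.15 without control 24 h b, 0.142 without control 24 h c, 0.0508 without TNF-alpha 24 h a, 0.0793 without TNF-alpha 24 h b and 0.182 without TNF-alpha 24 h c. For miR-146a-5p (1.225 to 1.5), 0.0693 without control 24 h a, 0.122 without control 24 h b, 0.159 without control 24 h c, 0.0508 without TNF-alpha 24 h a and 0.167 without TNF-alpha 24 h c. For miR-5106 (-0.83 to -1.02), 0.0737 without TNF-alpha 24 h a. For miR-485-3p (-0.50 to -0.80), 0.0522 without control 24 h b, 0.1 without control 24 h c, 0.178 without TNF-alpha 24 h b and 0.117 without TNF-alpha 24 h c. For miR-1957a (-0.55 to -0.61), 0.0515 without TNF-alpha 24 h a and 0.0799 without TNF-alpha 24 h c. For miR-540-3p (-0.50 to -0.60), 0.11 without control 24 h a, 0.217 without control 24 h b, 0.159 without control 24 h c, 0.0936 without TNF-alpha 24 h a, 0.178 without TNF-alpha 24 h b and 0.216 without TNF-alpha 24 h c. The count of 25 was 49 with only the libraries compared, 16 or 15 without control 24 h replicate b or c, and 14 without TNF-alpha 24 h replicate a or c. Of the inflammation list 6 rose and 0 fell (6 and 0 adjusted over the list alone) at 24 h (camera adjusted p = 2.5e-06), and of the miR-17-92 list 2 rose and 0 fell (2 and 0 adjusted over the list alone) (camera adjusted p = 0.00369, and adjusted p = 0.108 with an estimated correlation). miR-6237 went to 0.34 without TNF-alpha 12 h c.

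The TNF-alpha miRNA count at 72 h, 171 in the fit of all libraries, moved with the libraries fitted. With only the libraries compared it was 21, against 99 with IL-1beta. Without TNF-alpha 72 h replicate b 74 were called, and without control 72 h replicate c 105 were. Library totals moved the median of all miRNAs by -0.252 and took the share of called miRNAs that rose from 53.8% to 28.6% at 72 h, and from 52% to 70% at 24 h. Of the inflammation list 10 rose and 1 fell (10 and 1 adjusted over the list alone) (camera adjusted p = 2.2e-05), with miR-146a-5p (4.06 ± 0.42), miR-147-3p (2.44 ± 0.23), miR-222-3p (1.78 ± 0.12), miR-21a-3p (1.57 ± 0.14) and miR-155-5p (1.38 ± 0.11) among them. miR-221-5p (3.65 ± 0.56) and miR-146b-5p (2.44 ± 0.48) rose too, as did miR-183-5p (2.41 ± 0.61) and, with overlapping libraries, miR-99b-5p (2.44 ± 0.63). The edgeR adjusted p was, for miR-183-5p (0.79 to 2.87), 0.365 without TNF-alpha 72 h b; miR-99b-5p (1.30 to 2.94), 0.151 without TNF-alpha 72 h b. The largest falls were in miR-210-5p (-1.88 ± 0.20), miR-322-5p (-1.25 ± 0.13), miR-497a-5p (-1.16 ± 0.34), miR-210-3p (-1.04 ± 0.17), miR-540-3p (-1.03 ± 0.17) and miR-341-3p (-0.99 ± 0.16). The adjusted p was, for miR-497a-5p (-0.84 to -1.75), 0.0635 without control 72 h b, 0.124 without TNF-alpha 72 h b and 0.0585 without TNF-alpha 72 h c. Of the Dlk1-Dio3 miRNAs 1 rose and 10 fell (1 and 13 adjusted over the list alone) (camera adjusted p = 0.00252). Leading were miR-409-3p (-0.57 ± 0.11) and miR-300-3p (-0.53 ± 0.12). Of 17 tested cartilage miRNAs 1 rose and 3 fell (1 and 3 adjusted over the list alone), and the list passed for no comparison (camera adjusted p here = 0.835). miR-140-5p, the best known cartilage miRNA, fell (-0.66 ± 0.12), as did miR-140-3p (-0.71 ± 0.20). The adjusted p was, for miR-140-3p (-0.54 to -0.93), 0.0559 without control 72 h b and 0.0879 without TNF-alpha 72 h b. miR-146a-5p went to 3.26 without TNF-alpha 72 h b, miR-221-5p went to 2.60 without TNF-alpha 72 h b and miR-183-5p went to 0.79 without TNF-alpha 72 h b. miR-99b-5p went to 1.30 without TNF-alpha 72 h b and miR-497a-5p went to -1.75 without TNF-alpha 72 h a.

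**Figure D4:**
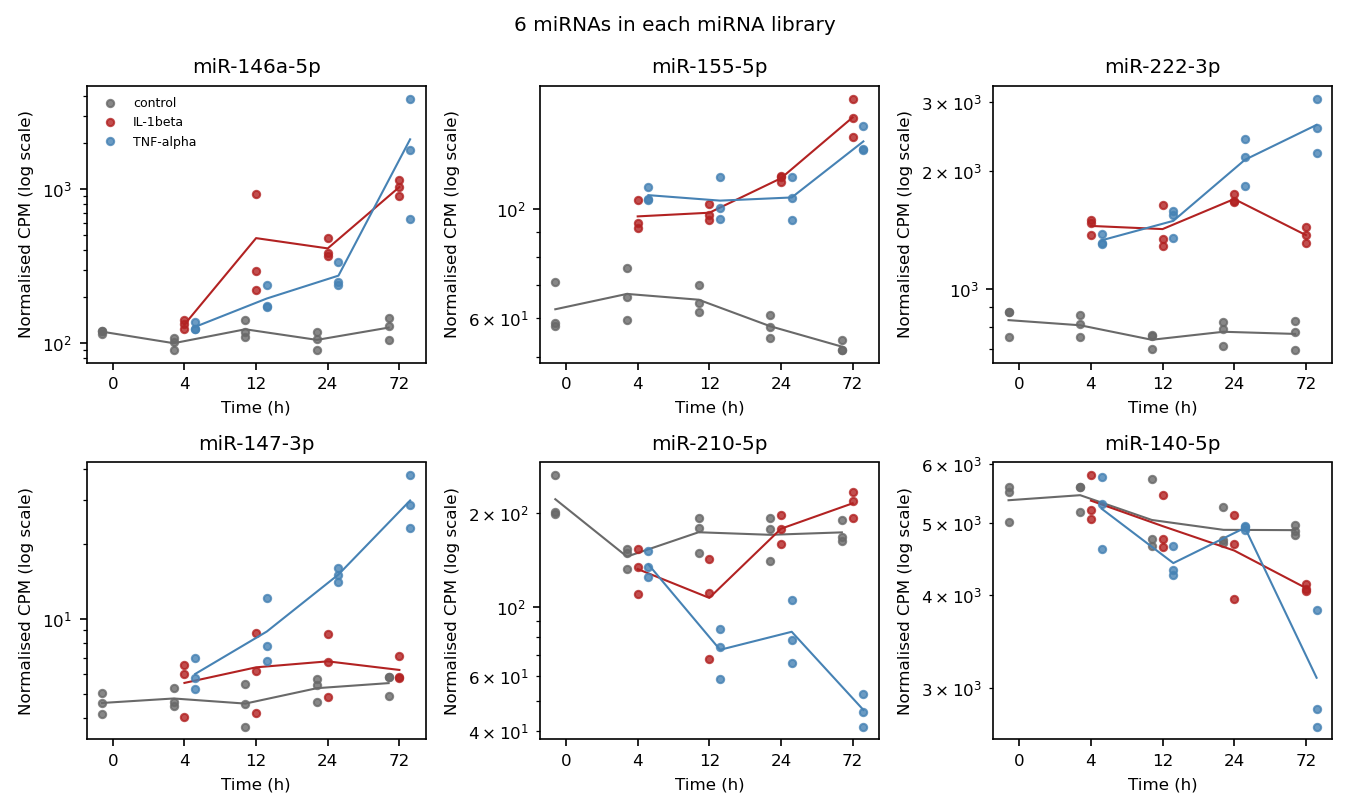
Normalised CPM (log scale) of 6 miRNAs in each miRNA library against time in h (evenly spaced); points are libraries, shifted sideways by treatment, and lines join group means. miR-222-3p lies above every control library of its time with both cytokines, and miR-210-5p with TNF-alpha at 72 h averages 46.8 CPM against 173 in the controls.

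Compared directly, 0 miRNAs differed between the cytokines at 4 h in edgeR (21 at an unadjusted p under 0.05) and 0 in DESeq2, and 1 differed without IL-1beta 4 h replicate c, 5 without the filter and 2 without IL-1beta 12 h b and TNF-alpha 72 h b. At 72 h 35 were higher and 96 lower with IL-1beta. Higher with IL-1beta were miR-138-5p (2.50 ± 0.31), miR-210-5p (2.19 ± 0.20), miR-802-5p (1.49 ± 0.18) and miR-210-3p (1.08 ± 0.17), and lower were miR-221-5p (-2.59 ± 0.53), miR-6240 (-2.28 ± 0.26) and miR-147-3p (-2.25 ± 0.23). Without TNF-alpha 72 h replicate b the count was 41, with only the libraries compared 9, without IL-1beta 72 h replicate b or c it was 80 or 87, and under library totals the median moved by 0.255 and the share higher went from 26.7% to 65.9%. At 24 h 5 were higher, miR-210-5p (1.09 ± 0.20), miR-802-5p (0.84 ± 0.18), miR-181a-1-3p (0.45 ± 0.10), miR-148a-5p (0.79 ± 0.19) and miR-5106 (0.87 ± 0.23), and 3 lower, miR-147-3p (-1.20 ± 0.23), miR-222-5p (-0.59 ± 0.13) and miR-341-5p (-0.88 ± 0.20). Only miR-210-5p kept its call without any 1 library, and in the order named the log2 fold changes of the other 7 were 0.76 to 0.96, 0.43 to 0.47, 0.67 to 0.89, 0.76 to 0.95, -1.005 to -1.38, -0.49 to -0.68 and -0.83 to -0.96. The count moved too: 1 miRNA was called without IL-1beta 24 h replicate a, 5 without its replicate c, and 3, 4 and 5 without TNF-alpha 24 h replicates a, b and c. Library totals gave 3 and took the share higher from 62.5% to 33.3%. At 12 h miR-21a-3p (0.58 ± 0.14) and miR-26a-2-3p (0.81 ± 0.20) were higher and miR-6237 (-2.05 ± 0.48), miR-341-5p (-0.84 ± 0.20) and miR-222-5p (-0.54 ± 0.13) lower, and none of the 5 kept its call without each library in turn. Their largest adjusted p was 0.555, 0.26, 0.579, 0.256 and 0.184 without 1 library, with log2 fold changes of 0.44 to 0.66, 0.78 to 0.83, -0.37 to -2.51, -0.71 to -0.97 and -0.43 to -0.63. The count was 13, 0 and 1 without IL-1beta 12 h replicates a, b and c, and 3, 1 and 0 without TNF-alpha 12 h replicates a, b and c. It was 12 in DESeq2, 17 without the filter, 3 with median-of-ratios factors, 3 under library totals, and 0 in edgeR with a replicate block or only the libraries compared. Library totals moved the median there by -0.147 and took the share higher from 40% to 0%. The let-7 list was higher with IL-1beta at 24 h though 0 of its 9 members were called (camera adjusted p = 0.00121, and adjusted p = 0.594 with an estimated correlation). miR-221-5p went to -1.54 without TNF-alpha 72 h b and miR-6237 went to -0.37 without TNF-alpha 12 h c.

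In untreated cartilage 1 miRNA was higher and 4 were lower at 72 h than at 0 h. With only the libraries compared 19 were called, without IL-1beta 12 h b and TNF-alpha 72 h b 21, in DESeq2 11 and without the filter 11. miR-322-5p rose (0.86 ± 0.13), and miR-27a-5p (-0.97 ± 0.11), miR-6240 (-1.58 ± 0.26) and miR-6937-5p (-1.41 ± 0.32) fell, with an edgeR adjusted p for miR-6937-5p (-1.29 to -1.55), 0.0735 without control 0 h b, 0.105 without control 72 h a and 0.14 without control 72 h c. miR-7a-5p was at 21 counts over the group at 0 h and 2 at 72 h, a ratio of 11.7-fold (counting interval 2.87 to 103). Library totals moved the median by -0.103. The Dlk1-Dio3 list was lower with 0 members called (0 and 2 adjusted over the list alone, camera adjusted p = 0.000582). The response differed between the 4 times for 28 miRNAs with IL-1beta, or 17 without control 72 h replicate c, and for 25 with TNF-alpha, or 89 without TNF-alpha 72 h replicate a. Without IL-1beta 12 h b and TNF-alpha 72 h b these were 51 and 41, and without the filter TNF-alpha gave 63. Over the 588 miRNAs the changes with the cytokines correlated at r = 0.704, 0.586, 0.668 and 0.585 at 4, 12, 24 and 72 h, against 0.537, 0.473, 0.501 and 0.508 in simulated sets without effect. At 72 h 21 miRNAs rose and 27 fell with both and 2 were called in opposite directions. The miR-29 (7 tested) and other-cell-type (5 tested) lists passed in no comparison, and no pluripotency miRNA had enough counts to be tested.

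**Figure D5:**
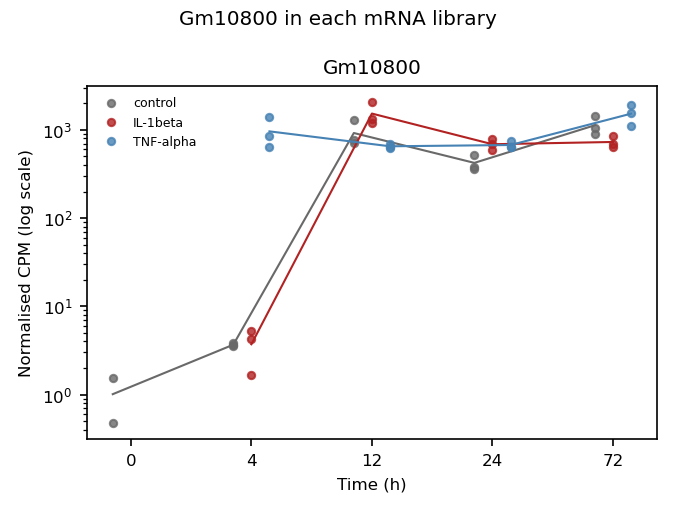
Normalised CPM (log scale) of the predicted gene Gm10800 in each mRNA library against time in h (evenly spaced); points are libraries, shifted sideways by treatment, and lines join group means. The 8 libraries of control 0 h, control 4 h and IL-1beta 4 h lie at 5.22 or less and the other 30 between 363 and 2068.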

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

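The tests of why a column stood apart, of the library parting and of the single library behind the TNF-alpha miRNA count at 72 h, and all counts over other splits, were chosen after the results were seen; the scaling test for miRNAs was written before. The size of the response differed between the 4 times for 7299 genes with IL-1beta and 3618 with TNF-alpha, and for 28 and 25 miRNAs, each by a test of the difference itself. For mRNA a fit of the IL-1beta and control libraries alone found 7445 genes, and 1 of 40 splits, the real one, gave as many (highest other 1947). With TNF-alpha the fit found 3438, and 1 of 40 splits, again the real one, gave as many (highest other 836). The splits shuffle cytokine and control labels within each time, which undoes the cytokine effect too. They therefore cannot exclude chance for a difference between times. For miRNA 10 of 100 splits gave as many as the 30 with IL-1beta (highest other 64) and 7 of 100 as many as the 26 with TNF-alpha (highest other 75), so chance is not excluded for either. The same limit holds here. A split that turns the labels around at only some times can make a steady cytokine effect look like a difference between times. Splits above the real count therefore do not show a structure of the miRNA libraries.

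Values outside the comparisons were found in the mRNA table: its nameless lines sum to 15490 counts, assigned here to control 0 h replicate b. That column stood apart on the named genes. A swapped or mislabelled whole library is argued against, since the column's highest correlation with any other library in place was 0.189, under the lowest between any 2 others (0.97). Low depth is argued against too, since replicate a thinned to the same total still correlated with replicate c at 0.882. A candidate explanation that stays open is that the counts follow another list of features and were set into the table by position: slid by 2008 to 2198 lines in the last 10 windows of 400, the column correlated with the others at up to 0.771, against 0.16 in place and 0.247 for a shuffled column. No biological explanation was tested.

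A set of 10 predicted, repeat-like genes parted 8 mRNA libraries (control 0 h, control 4 h and IL-1beta 4 h) from 30 others by over 3 on the log2 scale, of 20076 genes searched. Depth is argued against, since 28 libraries of the second set had totals within the range of the first. When the search left out the groups then compared, the same 10 genes came up, and time alone is argued against by their median difference of 6.41 between TNF-alpha and control at 4 h (lowest 4.85), and TNF-alpha alone by one of 7.48 between controls at 72 and 0 h (lowest 5.58). A batch of libraries, which may also carry part of the 4 h differences of TNF-alpha, cannot be told apart from the groups, since 0 groups had libraries on both sides, and a joint effect of time and TNF-alpha stays open, as untested. Control 0 h a and IL-1beta 4 h c, both of the first set, share an index sequence in their column names, as do control 0 h c and TNF-alpha 4 h b of opposite sets, so if an index was used once per pool the first set was not a single pool.

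The TNF-alpha miRNA count at 72 h was 171 in the fit of all libraries and 21 with only those compared. A few miRNAs taking most of the counts stay open: another scaling left at least 163 calls. The bound written beforehand wrongly used that count, since library totals took the share that rose from 53.8% to 28.6% and moved the median by -0.252. Replicate b is a candidate for part of the count, as 74 were called without it. Yet replicate SDs were 0.504, 0.537 and 0.382 in a, b and c against 0.25 to 0.272 in the controls. Their effect on the shared fit was not tested. A biological effect of TNF-alpha on the rest stays open, as a hypothesis.

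The other splits of the 6 libraries of a comparison, 10 with the real one, are too few for a share under 0.05, the smallest being 0.1. With these libraries alone the real splits for mRNA at 4, 12, 24 and 72 h called 5343, 4785, 6189 and 7630 genes with IL-1beta, 4302, 3603, 4635 and 6092 with TNF-alpha, and 1549, 908, 3625 and 7281 between them. The highest other split called 0 each time, so 1 of 10 was as large. For miRNA the real splits called 5, 0, 31 and 99 with IL-1beta (highest other 1, 0, 0 and 0; splits as large 1, 10, 1 and 1). They called 6, 7, 49 and 21 with TNF-alpha (highest other 17, 0, 0 and 0; as large 2, 1, 1 and 1), and 0, 0, 6 and 9 between them (highest other 13, 1, 0 and 0, as large 10, 10, 1 and 1). For the controls at 72 and 0 h the real miRNA split called 19, the highest other 7, and 1 was as large.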

How the results depend on the processing

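The fits with all 39 mRNA libraries, without 2 miRNA libraries, and on 1 side of the library parting were chosen after the results were seen, and the other tests before. The replicate letters were not treated as pairs: libraries of the same letter correlated at a mean of -0.000587 (mRNA) and 0.00313 (miRNA) after the group means were removed, and 9 of 38 and 14 of 39 were closest to their own letter. With the replicate letter as a block, 1272 values of named features kept their direction and call and 14 kept the direction only. For DESeq2 these were 1277 and 8, for median-of-ratios factors 1281 and 5, for library totals 1227 and 59, for no filter 1221 and 65. For only the libraries compared these were 1183 and 94, and for single libraries left out they were 7146 and 481. In none of these did a value reverse. With 2 miRNA libraries left out 128 kept the call and 20 did not. With all 39 mRNA libraries 797 kept it, 338 did not, and 2 reversed in control at 72 h against 0 h: Mmp14 (0.0597) and Wwp2 (0.04705).

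With all 39 mRNA libraries, the genes called at 4, 12, 24 and 72 h were 2848, 2722, 3029 and 4284 with IL-1beta, 1584, 2331, 2038 and 3330 with TNF-alpha and 685, 639, 1865 and 4342 between them. They were 4331 between controls, and 2994 and 739 for the differences between times. Only the count of 4331 uses control 0 h, so the others fell through an untested step of the shared fit. On only the fewer libraries compared, IL-1beta against TNF-alpha gave 1549 and 908 genes at 4 and 12 h. On 1 side of the library parting the TNF-alpha difference between times gave 1460 with 3 times instead of 4. The other alternatives left each mRNA count within 1.5 times, except that IL-1beta against TNF-alpha at 4 h gave 1431 genes without TNF-alpha 4 h replicate a.

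For miRNA more counts moved. Library totals gave 3 and 9 with IL-1beta at 4 and 12 h, and 3 and 3 between the cytokines at 12 and 24 h. Median-of-ratios factors gave 3 between them at 12 h, a replicate block 0 and DESeq2 12. DESeq2 gave 11 for control at 72 h against 0 h. Without the filter the counts were 15 with TNF-alpha at 4 h, 5 and 17 between the cytokines at 4 and 12 h, 11 between controls and 63 for the TNF-alpha difference between times, with more miRNAs tested. With only the libraries compared they were 0 with IL-1beta at 12 h, 49 and 21 with TNF-alpha at 24 and 72 h, 0 and 9 between the cytokines at 12 and 72 h, and 19 between controls. Without IL-1beta 12 h b and TNF-alpha 72 h b they were 6 with IL-1beta at 12 h, 9, 14 and 46 with TNF-alpha at 4, 12 and 24 h, 2, 0, 13 and 66 between the cytokines, 21 between controls, and 51 and 41 for the difference between times with IL-1beta and TNF-alpha. Apart from the fits on fewer libraries or more miRNAs, the cause was not tested.

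Leaving out 1 library at a time, where a lone pair of libraries was assumed to vary like the other groups, gave for mRNA at 4, 12, 24 and 72 h 4610 to 5713, 4712 to 5058, 5181 to 5455 and 6386 to 6645 genes with IL-1beta, 2762 to 3713, 4563 to 5002, 3787 to 4193 and 5883 to 6121 with TNF-alpha and 1431 to 2078, 1486 to 1933, 2943 to 3523 and 6602 to 6904 between them. It gave 5257 to 6650 between controls (a single 0 h library in some of these fits), and 6555 to 7217 and 2965 to 4107 for the differences between times. For miRNA it gave 3 to 5, 5 to 33, 15 to 20 and 58 to 72 with IL-1beta, 3 to 5, 4 to 10, 14 to 18 and 74 to about 2.2e+02 with TNF-alpha, 0 to 1, 0 to 13, 1 to 8 and 41 to 186 between them. Between controls it gave 4 to 6, and 17 to 35 and 17 to 89 for the differences between times. The libraries that moved a count by over 1.5 times are named in the report.

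Of the list results 316 kept their side of the threshold with an estimated correlation and 87 did not, 323 with fry, which passed 63 more and lost 5, and 394 with a replicate block, which passed 6 more. Directions that differed under fry had not passed: adjusted p = 0.806 (fibroblast, IL-1beta 12 h), 0.536 (muscle, TNF-alpha 72 h), 0.935 (let-7, IL-1beta 72 h), 0.807 and 0.935 (miRNA machinery and let-7, 72 h control). Between the cytokines they were 0.882, 0.883 and 0.973 (fibroblast, machinery, other-cell-type miRNAs, 4 h), 0.895 (NF-kappaB, 12 h), and 0.989, 0.836 and 0.911 (endothelial, immediate early, cartilage miRNAs, 24 h). With a replicate block the adjusted p of such lists was 0.979 and 0.979 (fibroblast and muscle, between the cytokines at 4 h) and 0.938 (adipocyte, 72 h control). Correlations of the responses at CPM of at least 10 were 0.785, 0.837, 0.669, 0.531 for mRNA at 4, 12, 24 and 72 h and 0.505 for miRNA at 12 h, on fewer features. Seed-site sets were not run. No test varied the depth, so what depth limits was not measured.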

Other observations

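The pairs of miRNAs and host genes were written after the data came, while the rule of this test was written before its result was seen. The hypothesis was that a miRNA changes with the host gene listed for it. Over 23 pairs with 13 host genes, the log2 fold changes in the 8 comparisons with control correlated at a mean of 0.119, against a median of 0.00859 for shuffled pairs (1-sided permutation p = 0.163, 100000 permutations). The test leaves the hypothesis open: the mean lay above the shuffled median but not above 95% of permutations. Single pairs ran from -0.589 (miR-17-5p and Mir17hg) to 0.948 (miR-485-5p and Mirg), with -0.263 for miR-155-5p and Mir155hg, which were both called in 7 comparisons, in the same direction in 7. Over all pairs 18 of 19 such cases had the same direction, a tally over comparisons with shared controls that was not tested.

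For the mRNA column of control 0 h replicate b no value of a named gene is used in the main fits. Among the miRNA libraries, miR-127-3p took 25.5% of counts in TNF-alpha 72 h replicate b and 23.4% in IL-1beta 12 h replicate b. The TMM factors of TNF-alpha 72 h replicates b and c were 0.677 and 0.773.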
